A study of Mus musculus with 4 samples.

How the data were processed

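Polyadenylated RNA of GFP-positive mesenchymal nephron progenitors, isolated by flow sorting from mouse kidney, was sequenced in 4 libraries, 2 from the BAC transgenic line Six2TGC and 2 from the knock-in line Six2Cre. Groups and replicate numbers were taken from the sample titles. Reads were aligned with HISAT2 and genes compared with Cuffdiff on the mm10 build, per the submitters' processing notes. Tool versions, trimming and the annotation used are not given in the sources used here. The authors deposited a gene table with an FPKM value per gene and library, and FPKM means per line, per the file headers. It also holds a test score, a p-value and a q-value of the authors' own comparison per gene, per the file headers. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be separated, and 5557 genes share their listed locus with another gene. FPKM corrects each value for gene length and library size, so values depend on which reads each gene was assigned, and reads that match several gene copies were divided among them in a way the files do not record.

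The table holds 24339 genes, and 1 line is not used here. Symbols of 27 genes had been turned into dates by a spreadsheet and were not named in the text, and 102 lines hold several symbols. The deposited fold change column had 506 cells with spreadsheet errors, so fold changes were computed from the FPKM values. Coordinates in the table are counted from 0 and were raised by 1 at the start. Of 23142 symbols found in the RefSeq gene table of the same build, 11862 then had the same start and 11769 the same end. Gene types came from GENCODE M21.

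Depth was estimated because the table holds no counts. For genes with FPKM up to 0.4 in all libraries, the most frequent ratio between libraries was taken as the ratio of single fragments. Not all low values are whole fragments, and only 334 of 1309, 256 of 1497 and 252 of 1511 genes compared lay in the peak. The ratios gave depths of 0.958 (Six2TGC replicate 2), 1.85 (Six2Cre replicate 1) and 1.88 (Six2Cre replicate 2) relative to Six2TGC replicate 1. Genes with a single transcript of over 2000 bases and a value in only 1 library gave about 7.40e+06, 7.11e+06, 1.36e+07 and 1.38e+07 fragments. These rest on few genes (9 of 23 in the peak for Six2TGC replicate 1) and carry no interval. Genes listed at 0 numbered 8777, 8964, 8168 and 8209, and a listed 0 is not evidence of absence. No value above 0 was equal between any pair of libraries, so none was a duplicate.

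Genes with a mean FPKM of at least 1 over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend and robust empirical Bayes, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Effects are Six2TGC over Six2Cre, and fold changes on this scale understate the change of low genes. Folds in the text are ratios of mean FPKM, and none is given against a line listed at 0. No covariate was used, and the library names run apart between the lines with no date given, so any batch cannot be told apart from the line. The 32 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01. The p-values were adjusted over the 25 lists with at least 5 tested members. None of the 14 calls held with an estimated correlation, a setting that also leaves the test few degrees of freedom with 4 libraries. The immediate early list, with an estimated correlation of 0.0111, went from p = 1.2e-12 to 0.0195 in limma camera. Losses under that setting therefore do not show that correlation between genes undid the calls. Of 495 list symbols, 494 were found. Calls of list members are given over all genes tested and adjusted over the list alone.

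Genes named in the text were 14 fixed before the data were examined, the 12 largest rises and 12 largest falls among called genes whose libraries separate the lines and whose symbol is not a predicted-gene name, and up to 4 called members of each list with the largest changes. Others, named where a count of 5 or fewer or a contrast needed them, were chosen after their values were seen, among them Fgf8, Tmem100, Capn6, Axin2, Cdh11, Hoxd11, Srbd1, Camkmt, Prepl, Prkce, Hspa1a, Hspa1b, Otx2, Cdh5, Pecam1, Tie1, Slc3a1, Kdm5d and Eif2s3y.

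The test was run on 10 simulated data sets of 11917 genes with 200 changed. With spreads drawn from the fitted model, it recovered 91.3% of genes changed by 1 on the log2 scale and 99.7% of those changed by 2, with 5.65% false calls among all calls. With spreads redrawn from the fitted genes, the shares were 97.1%, 99.5% and 12.9%, so calls near the threshold are less certain than the nominal rate. Camera recovered 10 of 10 changed lists and called 0 unchanged ones. Every member of a changed list had been raised by 1 or 2 on the log2 scale, so recovery was easy. The runs do not show how camera does on lists with mixed or small changes, or where many more genes differ. Genes were drawn independently of each other in these runs. They therefore cannot show how camera at the preset correlation behaves on lists whose genes correlate, such as the proximal tubule list (estimated correlation 0.929). Alternatives covered the pseudocount, the filter, 3 scalings, the replicate block, each library left out in turn, plain empirical Bayes, other thresholds and set tests, the authors' own test, and 2 gene filters chosen after seeing the data. A fit with a library left out has a lone library in that line and less information on spread. A call lost there need not mean a smaller change. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.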

Results

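The data set compared mouse kidney nephron progenitors from a pair of lines that make a GFP-Cre fusion protein under control of Six2, a transcription factor gene active in the progenitors that give rise to the nephron. Six2TGC carries the fusion on a bacterial artificial chromosome (BAC) transgene, and Six2Cre carries it as a knock-in at Six2 itself, heterozygous per the labels. GFP-positive cells were sorted by flow cytometry and their polyadenylated RNA was sequenced, with 2 libraries per line and 4 libraries in all. The labels do not say whether the libraries of a line came from separate animals, so the p-values measure only the spread between these samples. The deposited FPKM values summed to 483087 and 481665 in the Six2TGC libraries and to 549971 and 537366 in the Six2Cre libraries. Depth estimated from low values relative to Six2TGC replicate 1 was 0.958 in Six2TGC replicate 2 and 1.85 and 1.88 in the Six2Cre libraries, so genes near the detection limit were measured less precisely in Six2TGC. Across genes, which are not independent replicates, log2 values correlated at r = 0.982 between the Six2TGC libraries and 0.984 between the Six2Cre libraries, and at 0.948 to 0.952 between libraries of different lines. The Y-linked gene Ddx3y stood at FPKM 12.7 in Six2TGC replicate 1 and was listed at 0 in the other libraries, while Xist, the RNA of the inactive X chromosome, stood at 0.0107 in that library and at 75.7, 56.7 and 60.6 in Six2TGC replicate 2 and both Six2Cre libraries. The Six2TGC libraries thus came from different animals or pools, and these genes do not tell whether the Six2Cre libraries did.

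The comparison of the lines asked how progenitors that express GFP-Cre from the BAC transgene differ in their transcripts from those that express it from the knock-in. Six3, a homeobox gene best known from forebrain and eye development, stood at FPKM 107 and 106 in the Six2TGC libraries and was listed at 0 in both Six2Cre libraries. Wnt4, which drives the conversion of progenitors into epithelium, was 11.2-fold higher in Six2TGC, at 115 ± 6.86 against 10.3 ± 1.30 (SD, n = 2 per line). Cited1, a marker of the least differentiated progenitors, was 8.77-fold lower, at 102 ± 10.1 against 892 ± 20.7. Six2 itself was 1.45-fold higher in Six2TGC, at 782 ± 47.7 against 539 ± 8.45. Because the heterozygous knock-in of Six2Cre lies at Six2, an effect of the altered allele on Six2 cannot be told apart from other differences between the lines. Nor do values per gene separate reads of any gene copy on the BAC transgene from reads of the native gene, for Six3 as for Six2. Immediate early genes such as Fos, Junb and Nr4a1 were lower in Six2TGC.

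Of 11917 genes tested, 2900 differed between the lines (limma, Benjamini-Hochberg adjusted p under 0.05), with 1286 higher and 1614 lower in Six2TGC. Of these, 483 changed by at least 1 on the log2 scale, 263 higher and 220 lower. In the authors' deposited table, 1637 of 12158 tested genes were significant, 844 higher and 793 lower in Six2TGC. The tests shared 1441 genes, all 1441 in the same direction. Both libraries of one line lay above both of the other for 65.9% of tested genes, where chance gives 33.3%. The count fell to 1010 without Six2Cre replicate 1 and to 1143 without Six2Cre replicate 2. The balance of calls moved with level. At a mean log2(FPKM + 1) below 3, 392 genes were higher and 367 lower in Six2TGC, from 3 to 6 737 and 868, and from 6 to 9 152 and 295 of 1186 tested, with a median of -0.09. Of 114 genes above 9, 84 were lower and 5 higher in Six2TGC, with a median of -0.39. TMM rescaling and quantile normalization turned the majority of calls from lower to higher, with 50.2% and 51.8% of calls higher against 44.3%.

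**Figure D1:**
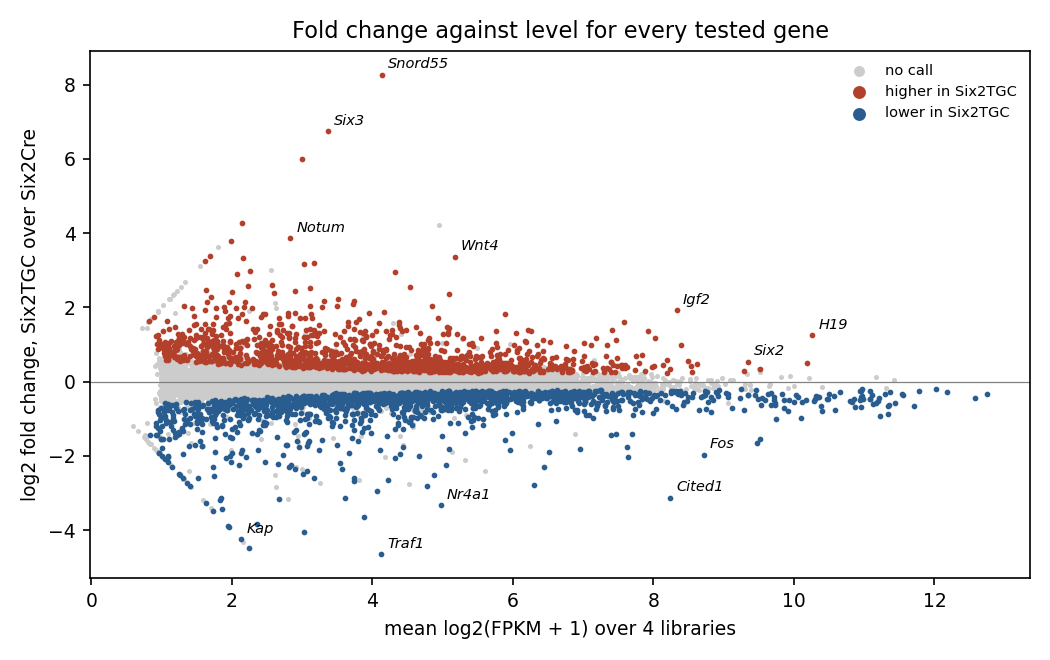
Each point is a tested gene, with its mean log2(FPKM + 1) over the 4 libraries on the x axis and its log2 fold change, Six2TGC over Six2Cre, on the y axis. Red points were called higher and blue points lower in Six2TGC; Six3 lies at 6.74 and Cited1 at -3.12, and the points at the far right are mostly blue.

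Six3 lies on chromosome 17 at 85620834 to 85626191 (mm10), and Six2 on the same chromosome at 85684268 to 85688254. The noncoding gene Six3os1, at 85601932 to 85618396 beside Six3, stood at FPKM 12.4 and 15.3 in Six2TGC and at 0.0706 and 0.0594 in Six2Cre. Six3 (log2 fold change 6.74 on the log2(FPKM + 1) scale, limma adjusted p = 5.80e-08), Six3os1 (3.80, 1.29e-05) and Six2 (0.54 ± 0.0664 SE, 1.57e-03) were the higher members of the fixed list of Six2 and its neighbours on the chromosome. Of 12 tested members of that list, 3 were higher, 1 lower and 8 had no call, and adjusted over the list alone 3 were higher and 2 lower. Dync2li1 fell by 0.38 on the log2 scale, a call lost without either Six2Cre library, and the flanking genes Srbd1 (-0.14), Camkmt (-0.16), Prepl (-0.11) and Prkce (-0.32) had no call. Slc3a1, listed at the same locus as Prepl, had none either, at -0.91, with FPKM 0.528 and 0.311 in Six2TGC and 2.62 and 0.960 in Six2Cre. The list had no camera call (limma camera, adjusted p = 0.496), and its median of -0.09 became -0.15 without Six2Cre replicate 1. Six3 was the single tested member of the anterior neural and eye field list, and Otx2 was listed at 0 in all 4 libraries. Among 10 tested genes of the families of Six2, Eya1 and Dach1, 5 were higher and 2 lower, with the same counts adjusted over the list alone. Besides Six3, the largest changes were Dach2 (1.29), Eya2 (-0.91) and Dach1 (0.89). The family list was called higher (limma camera, adjusted p = 0.0133), and the call was lost at adjusted p = 0.331 with an estimated correlation and at 0.114 in limma camera on the scores of the authors' deposited table.

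Nephron progenitor markers were mostly lower in Six2TGC: of 24 tested, 5 were higher, 15 lower and 4 had no call, and adjusted over the list alone 7 were higher and 16 lower. Besides Cited1 (log2 fold change -3.12 ± 0.0832 SE, limma adjusted p = 3.66e-06), the largest falls were in Traf1 (-4.64), the homeobox genes Meox2 and Meox1 (-1.83) and Tmem100 and Capn6. Traf1, a signalling adaptor, stood at 2.75 ± 1.90 in Six2TGC against 86.4 ± 1.48 in Six2Cre, and Meox1 at 17.4 ± 4.51 against 63.4 ± 1.30 (SD, n = 2). Smaller falls were found for Gdnf (-0.41), the ligand that draws the ureteric bud, for Wt1 (-0.36) and for Eya1 (-0.29). Osr1 had no call, at 61.0 ± 11.8 against 60.5 ± 2.54. Hoxc11, Fgf20, Six2, Cdh11 and Hoxd11 were the 5 higher members. The list median was -0.34 and the list was called lower (limma camera, adjusted p = 9.46e-03), with adjusted p = 0.314 with an estimated correlation. The Traf1 call was lost without Six2Cre replicate 1, where its log2 fold change was -4.62. The Gdnf and Wt1 calls were lost without either Six2Cre library, with Gdnf at -0.41 in both fits and Wt1 at -0.35 and -0.37. The Hoxc11 call was lost without either Six2TGC library, at 1.47 and 1.32. Eya1 kept its call only when Six2TGC replicate 2 was the library left out, and lost it under TMM rescaling (limma adjusted p = 0.0534).

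Markers of early differentiating nephron structures moved the other way. Of 15 tested, 11 were higher, 3 lower and 1 had no call, and adjusted over the list alone 11 were higher and 4 lower. Wnt4 rose by 3.37 on the log2 scale (limma adjusted p = 4.11e-06), and Lhx1, a transcription factor of the renal vesicle, by 1.99 from 1.09 ± 0.120 to 7.33 ± 0.948. The cadherin genes Cdh6 (2.16) and Cdh4 (2.03) and the Wnt effector Lef1 (2.05) also rose. The lower members included Fgf8 (-1.96) and the Notch ligand gene Dll1 (-1.53), so the list was not uniform. Its median was 1.17, with a call higher (limma camera, adjusted p = 6.57e-05) and adjusted p = 0.314 with an estimated correlation.

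**Figure D2:**
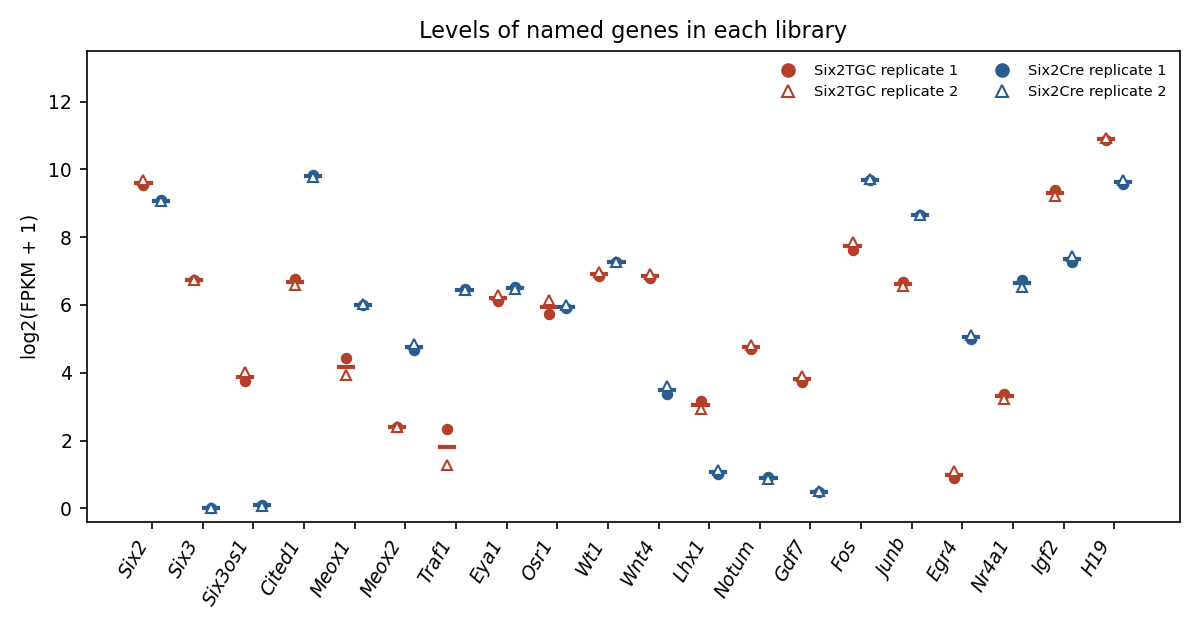
Levels of 20 named genes as log2(FPKM + 1), with a point for each library (circles replicate 1, triangles replicate 2) and a bar at the mean of each line. Red is Six2TGC and blue Six2Cre; Six3 lies at 0 in both Six2Cre libraries, Wnt4 is higher and Cited1 lower in both Six2TGC libraries, and Osr1 overlaps between the lines.

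Wnt pathway target genes rose together in Six2TGC, with 10 of 12 tested members higher, 0 lower and 2 without a call, and the same counts adjusted over the list alone. Notum, which encodes a secreted inhibitor of Wnt proteins, was 30.4-fold higher, at 26.1 ± 1.59 against 0.859 ± 0.0333 (SD, n = 2). Sp5 rose by 2.61 and Axin2, a general readout of the pathway, by 0.49. The list median was 0.82 (limma camera, adjusted p = 2.34e-07), with adjusted p = 0.279 with an estimated correlation. Wnt4, Lef1 and Ccnd1 are also in the early differentiating nephron list, so the calls of these lists are not independent. BMP and TGF-beta pathway genes were also higher, 9 of 16 tested with 0 lower, and 11 and 0 adjusted over the list alone. Bmper (1.33), Bmp4 (1.27), Smad9 (1.12) and Id4 (0.88) led that list, whose median was 0.51 (limma camera, adjusted p = 8.38e-07, with adjusted p = 0.343 with an estimated correlation). Among Notch pathway genes, 5 of 13 were higher and 1 lower (5 and 3 adjusted over the list alone). The largest changes were in Dll1 (-1.53), the lower member, and Jag1 (1.38). The Notch list had no call (limma camera, adjusted p = 0.0982) but was called higher among genes with a mean FPKM of at least 5, with a median of 0.52 (7.15e-03). The FGF and MAPK feedback list had no call either (adjusted p = 0.121 in limma camera, 0.0164 and called higher at a mean FPKM of at least 5), with 7 of 17 higher and 2 lower, and 8 and 5 adjusted over the list alone. Its ligand genes went apart, Fgf20 by 1.15 and Fgf9 by -1.26.

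Immediate early and dissociation stress genes were lower in Six2TGC as a group. Of 19 tested, 0 were higher, 14 lower and 5 had no call, and 15 were lower adjusted over the list alone. Fos, a rapidly induced transcription factor gene, stood at 213 ± 24.8 against 832 ± 5.74, Junb at 97.5 ± 4.74 against 405 ± 0.102 and Nr4a1 at 8.92 ± 0.718 against 98.6 ± 9.66 (SD, n = 2). The related genes Egr4 (-4.05) and Egr3 (-3.65), outside the list, were among the 12 largest falls of all, and the Egr3 call was lost without either Six2Cre library. The list median was -1.54 (limma camera, adjusted p = 3.04e-11), with adjusted p = 0.279 with an estimated correlation. Heat-shock genes Hspa1a and Hspa1b in the list had no call in limma but were significant in the authors' deposited table (q = 8.73e-04 for each), with Hspa1b at 2.54 and 2.86 in Six2TGC and 14.8 and 37.9 in Six2Cre. Unfolded protein and integrated stress response genes had no list call (limma camera, adjusted p = 0.121), with 0 of 16 higher and 5 lower, and 1 and 6 adjusted over the list alone. Without Six2TGC replicate 2 that list was called lower (limma camera, adjusted p = 0.0197). Atf3 (-1.50), Ddit3 (-0.99) and Atf4 (-0.89) were the largest changes there, and Atf3 is also in the immediate early list.

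The growth inhibitor gene Cdkn1a was 2.76-fold higher in Six2TGC, at 35.3 ± 2.09 against 12.8 ± 0.357 (SD, n = 2; log2 fold change 1.39, limma adjusted p = 7.79e-05). It was the single higher gene among 18 tested p53 targets, of which Btg2 (-2.79) and Phlda3 (-0.77) were lower, with the same counts adjusted over the list alone and no list call (limma camera, adjusted p = 0.690). Btg2 is also in the immediate early list. Of 20 G2 and M phase genes, 12 were lower and 0 higher, and 14 were lower adjusted over the list alone. Ube2c (-0.66) and Nusap1 (-0.57, no call without Six2Cre replicate 2) led, and the list was called lower with a median of -0.34 (limma camera, adjusted p = 1.15e-05, with adjusted p = 0.343 with an estimated correlation). Of 20 S phase genes, 5 were lower and 0 higher, and 9 were lower adjusted over the list alone, with Rrm2 at -0.64 and no Rrm2 call without either Six2Cre library. That list's call (limma camera, adjusted p = 0.0177, with adjusted p = 0.559 with an estimated correlation) was lost without Six2TGC replicate 1, at 0.251, and without Six2Cre replicate 2, at 0.105. Its median of -0.14 became -0.07 without Six2TGC replicate 1 and -0.25 without Six2TGC replicate 2. Apoptosis genes had no call (adjusted p = 0.158 in limma camera), with 1 of 17 higher and 4 lower, and 2 and 5 adjusted over the list alone, and the survival gene Mcl1 fell by 0.81. None of 6 tested interferon-stimulated genes was called, over all genes or adjusted over the list alone, and the list had no call (limma camera, adjusted p = 0.525).

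Cytosolic ribosomal protein genes were lower in Six2TGC, 20 of 25 tested with 0 higher, and 21 lower adjusted over the list alone. Rpl19 fell by 0.79 and Rpl32 by 0.67, the latter from 4198 ± 29.1 to 2647 ± 61.3 (SD, n = 2). Reads of these genes can be shared with their many pseudogenes, so single values are uncertain. Of 21 oxidative phosphorylation genes, 8 were lower and 0 higher, and 12 were lower adjusted over the list alone, led by Cycs (-0.57, no call without either Six2Cre library). Medians were -0.42 for the ribosomal list (limma camera, adjusted p = 2.45e-10, with adjusted p = 0.279 with an estimated correlation) and -0.22 for the oxidative list (2.57e-04, with adjusted p = 0.279 with an estimated correlation). Quantile normalization ended both calls, with a median of -0.04 and adjusted p = 0.159 for the ribosomal list and -0.11 and 0.130 for the oxidative list in limma camera. Of all 114 tested genes above 9 in mean log2(FPKM + 1), 84 were lower in Six2TGC, with a median of -0.39. Camera did not match genes on level, so the ribosomal call is not shown to be separate from that shift of highly expressed genes. Glycolysis and hypoxia genes were called higher (limma camera, adjusted p = 9.20e-03, with adjusted p = 0.496 with an estimated correlation), with 4 of 18 higher and 1 lower, and 8 and 1 adjusted over the list alone. The glucose transporter gene Slc2a1 rose by 0.76 and Hk2 by 0.53, while Gapdh, which shares sequence with pseudogenes, fell by 0.70. The Slc2a1 call was lost without Six2Cre replicate 2 and the Gapdh call without Six2Cre replicate 1. The list call was lost without Six2TGC replicate 1 (limma camera, adjusted p = 0.0801), and the median of 0.17 became 0.29 without Six2TGC replicate 2. Cholesterol synthesis genes had no call (limma camera, adjusted p = 0.0982, 0.0443 and called higher at a mean FPKM of at least 5), with 4 of 19 higher and 1 lower, and 5 and 1 adjusted over the list alone, and the regulator gene Srebf2 rose by 0.56, a call lost without Six2Cre replicate 1.

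Fetal growth and imprinted genes were higher in Six2TGC, 7 of 15 tested with 1 lower, and 8 and 1 adjusted over the list alone. The growth factor gene Igf2 was 3.83-fold higher, at 629 ± 52.5 against 164 ± 15.1, and its neighbour H19, a noncoding RNA gene, 2.38-fold higher, at 1892 ± 57.1 against 795 ± 47.8 (SD, n = 2). Igf2r rose by 0.77, and Mest, another imprinted gene, fell by 1.02. The median was 0.34 (limma camera, adjusted p = 4.14e-04, with adjusted p = 0.279 with an estimated correlation). Posterior Hox genes had no list call (limma camera, adjusted p = 0.0778), with 5 of 15 higher and 3 lower in both adjustments, and Hoxc11 (1.39), Hoxb9 (-1.23) and Hoxd12 (1.20) went in different directions. The list was called higher without Six2TGC replicate 2 (limma camera, adjusted p = 0.0402) and at a mean FPKM of at least 5 (0.0498).

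Markers of other kidney cells differed between the lines as well. Of 9 tested proximal tubule markers, 7 were lower in Six2TGC and 0 higher, and 8 were lower adjusted over the list alone. The phosphate transporter gene Slc34a1 stood at FPKM 0.0872 and 0.364 in Six2TGC and at 14.6 and 6.24 in Six2Cre. The list median was -1.43 (limma camera, adjusted p = 1.17e-04, with adjusted p = 0.430 with an estimated correlation), and Slc34a1 and Slc27a2 lost their calls without either Six2TGC library. The list median became -2.31 without Six2Cre replicate 2, -2.15 at a mean FPKM of at least 5, and -2.02 and -3.62 with a pseudocount of 0.5 and 0.1. Stromal markers were higher, 6 of 16 tested with 2 lower, and 7 and 2 adjusted over the list alone. Foxd1, the regulator of the stromal lineage, stood at 56.1 ± 1.20 against 35.3 ± 2.91 (SD, n = 2; log2 fold change 0.66, limma adjusted p = 1.79e-03), and Penk rose by 1.53. The stromal median was 0.66 (limma camera, adjusted p = 1.80e-03, with adjusted p = 0.343 with an estimated correlation). The podocyte list had no call (limma camera, adjusted p = 0.113, 0.0228 and called higher at a mean FPKM of at least 5), with 2 of 7 higher and 1 lower in both adjustments, including Clic5 (-1.40, no call without Six2Cre replicate 1). The ureteric epithelium list had none either (adjusted p = 0.377 in limma camera, 0.0124 and called lower without the filter), with 1 of 5 higher and 3 lower in both adjustments, including Wnt11 (1.38) and Krt18 (-2.26).

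Lists with fewer than 5 tested members were counted without a list test. Umod of the loop of Henle was lower, 1 of 2 tested members, at 0.577 and 0 in Six2TGC and 2.38 and 1.63 in Six2Cre. Its call was lost with a pseudocount of 0.1 (limma adjusted p = 0.0641), and Umod was not significant in the authors' deposited table (q = 0.532). Adjusted over the list alone, that list had 1 higher and 1 lower member. Plvap was the single higher gene of 4 tested endothelial markers (1 higher and 1 lower adjusted over the list alone), while the endothelial genes Cdh5 and Pecam1 had a mean FPKM under 1 and were not tested. Pecam1 stood at 0.222 and 0.0463 in Six2TGC and 0.645 and 0.965 in Six2Cre, Cdh5 at 0.267 and 0.105 against 0.918 and 1.12, and Tie1, also not tested, at 0.138 and 0.0359 against 0.740 and 1.32. Without either Six2Cre library the Plvap and Hbb-bt calls were lost, as was the Nefm call without Six2Cre replicate 1. C1qa (1.24) was higher and Cd68 (-1.18) lower, the 2 tested immune markers, with the same counts adjusted over the list alone. The globin gene Hbb-bt was the single higher gene of 2 tested erythroid markers, and Elavl4, Nefl and Nefm were lower, 3 of 4 tested neuronal markers, both with the same counts adjusted over the list alone. None of the 3 tested Y-linked genes was called in limma, while Ddx3y, Kdm5d and Eif2s3y were significant in the authors' deposited table (q = 8.73e-04 for each).

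**Figure D3:**
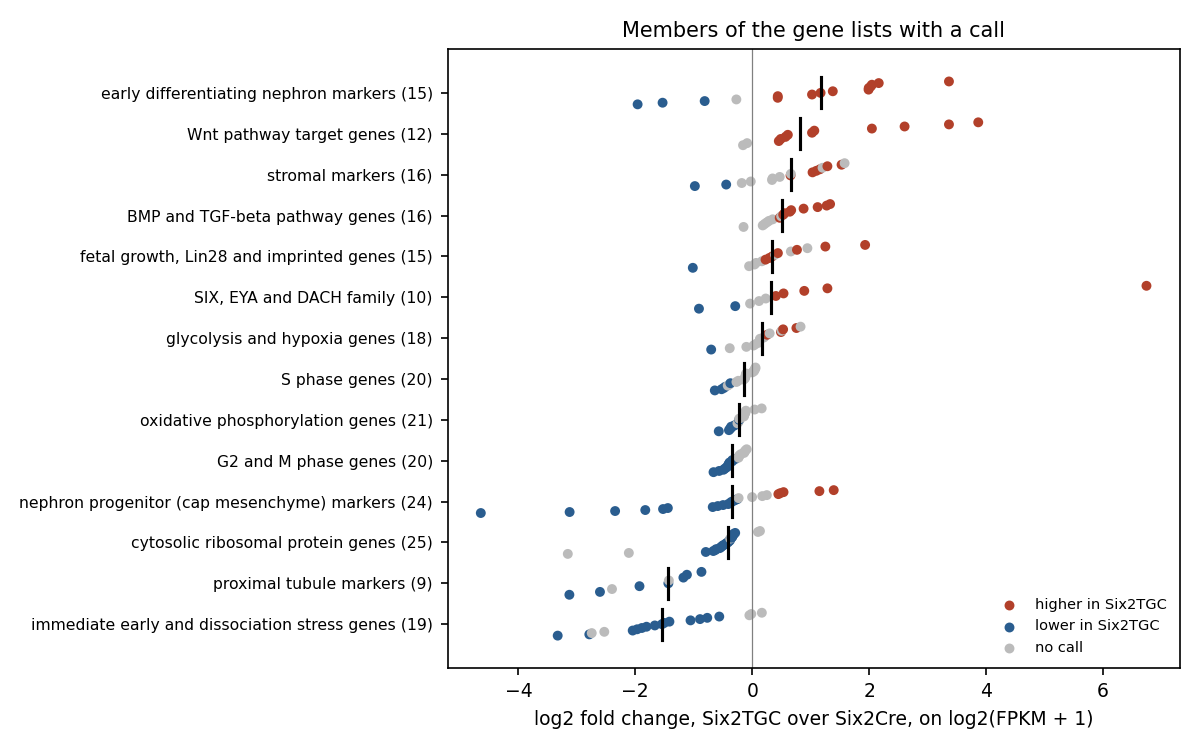
Log2 fold changes, Six2TGC over Six2Cre, of the tested members of the 14 lists with a camera call. Each point is a gene, red if called higher, blue if called lower and grey if not called, black bars are list medians, and the number of tested members is in brackets; medians run from -1.54 for immediate early genes to 1.17 for early differentiating nephron markers.

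Among the 12 largest rises and 12 largest falls of genes with an assigned symbol, further protein genes were found on both sides. Nxph1 stood at 16.2 and 20.9 in Six2TGC and was listed at 0 in both Six2Cre libraries. Gdf7, a BMP family ligand gene, was 32.0-fold higher, Fzd10, a Wnt receptor gene, 17.7-fold, Pianp 13.4-fold and Cldn11, a tight junction gene, 13.4-fold (limma adjusted p at most 2.08e-04 for each). Among the falls, Kap, a kidney androgen-regulated gene, was listed at 0 in both Six2TGC libraries and stood at 22.6 and 14.4 in Six2Cre. Siglecg fell by 3.83 on the log2 scale. The short RNA genes Snord55, Mir3063 and Mir8101 among the rises and Mir5131, Mir6992, Snora3 and Snora33 among the falls, with the histone gene Hist1h2ao, were significant in limma but not in the authors' deposited table. Their values are uncertain, since such genes are shorter than the sequenced fragments or lie within or match other genes.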

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

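The filters on genes the authors tested and on short RNA genes were chosen after seeing the data, and the other alternatives before. The 2900 changed genes became 483 with a log2 fold change of at least 1 and 1637 in the authors' deposited test, with the cause not tested. Leaving out a library, which assumes the lone library varies like the others, gave 1010 to 2803, lowest without Six2Cre replicate 1 (1010, of which 946 were among the 2900) and without Six2Cre replicate 2 (1143), with the cause not tested. The replicate numbers do not pair the libraries (correlation of deviations -0.04), and the replicate block gave 2713 genes, 2553 of them shared. The other settings stayed within 1.5 times. Among the lists, 14 had a call; 0 had one with an estimated correlation, 18 had one without the filter, 18 (12 higher, 6 lower) at a mean FPKM of at least 5, 14 in fry, of which 10 were shared, and 11 in the authors' test, where the list of the families of Six2, Eya1 and Dach1 (limma camera, adjusted p = 0.114), S phase (0.0981) and glycolysis (0.0762) lists lost theirs, and leaving out a library gave 12 to 16. In fry the lists of Six2 neighbours, Notch pathway, posterior Hox and apoptosis genes gained a call, and the proximal tubule (adjusted p = 0.0833 in limma fry), stromal (0.0760), S phase (0.212) and glycolysis (0.120) lists lost theirs. The share of calls higher in Six2TGC, 40.7 to 50.8% over left-out libraries, changed side with TMM rescaling (50.2%), quantile normalization (51.8%) and without Six2Cre replicate 1 (50.8%), with the cause not tested. Xist ranged from -5.88 without Six2TGC replicate 2 to 0.36 without Six2TGC replicate 1, the library with Y-linked reads (limma adjusted p = 0.0318). Osr1, without a call, changed sign at 0.0274 (TMM), 0.00698 (median centring), 0.0242 (quantile), 0.0399 (without Six2Cre replicate 2) and 0.0106 (authors' test), and ranged from -0.20 to 0.19 (without Six2TGC replicate 1) over left-out libraries. The direction given by the list test, not the sign of the median, turned for p53 targets without a call (medians 0.0189 at a mean FPKM of at least 5, 0.0661 in fry, 0.0842 in the authors' test) and interferon genes (-0.0119 without Six2TGC replicate 2, with -0.306 without Six2TGC replicate 1 the lowest). The block ended gene calls that included Eya1, Bid and Apaf1, and no list call. Besides short RNA, histone and Umod calls, Eya1, Wt1, Gdnf, C1qa, Hbb-bt, Dync2li1, Ddit3 and Gapdh, named as changed, were not significant in the authors' deposited test. Plain empirical Bayes ended the calls of Eya1, Wt1, Gdnf and Rrm2. Count-based tests were not run, since the table holds FPKM. The lower depth of Six2TGC limits genes at low FPKM.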

Other observations

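The added lists of heat-shock, further proximal tubule and committed nephron genes were chosen after the main results were seen, as were the genes and the Hox clusters described next and the medians without shared genes and their intervals. Of 8 tested Hoxb genes on chromosome 11, 6 were lower in Six2TGC and 0 higher, with a median log2 fold change of -0.61, and of 7 tested Hoxc genes on chromosome 15, 6 were higher and 0 lower, with a median of 0.63. These Hoxb and Hoxc counts were the same under TMM rescaling, median centring and quantile normalization. Of 9 Hoxa genes 1 was higher and 1 lower, and of 7 Hoxd genes 2 were higher. The difference between clusters was not itself tested.

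Single genes outside the fixed lists, not tested as a group, follow. Slit2, a guidance ligand gene, stood at FPKM 54.9 ± 5.86 in Six2TGC against 8.61 ± 1.12 in Six2Cre, and Slit1 at 33.4 ± 4.56 against 8.44 ± 0.928 (SD, n = 2), while Slit3 fell by 0.76 on the log2 scale. Vegfc rose by 2.52, the BMP antagonist gene Nog by 1.71, Scube3 by 2.95 and the retinoid enzyme gene Rdh10 by 1.83. In the major histocompatibility region, H2-K1 fell by 1.85 and H2-Ab1 by 1.19, while H2-Q7 rose by 1.72.

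Immediate early genes were lower in Six2TGC, with a list median of -1.54. Scaling is argued against, since the highest median under 4 scalings was -1.35. Rescaling does not change how many fragments were read, so depth was not tested. For lower FGF and MAPK output, the biological explanation weighed, the pathway's feedback list met the bound set against it. Its median was 0.16 (bootstrap 95% interval over members -0.21 to 0.32). That list also holds ligand and receptor genes, so its median is not a measure of output alone. Of 17 tested members, 7 were higher, among them Spry1 (0.59), and 2 lower, Fgf9 (-1.26) and Etv1 (-0.90). Lower output is therefore not excluded. Handling stress stays open: the heat-shock list had a median of -0.51, but without Hspa1a and Hspa1b, which both lists hold, it was -0.42, between the bounds set for and against. Handling cannot be told apart from the line, because no label records how each sort was done.

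For the lower proximal tubule genes in Six2TGC, a larger share of every other kidney cell type in the Six2Cre libraries is argued against by the stromal list alone, with a median of 0.66 (interval 0.22 to 1.16, which excludes 0 but reaches below the bound of 0.25 set beforehand), though its limma camera call was lost with an estimated correlation (adjusted p = 0.343) and in fry (0.0760), as was that of the proximal tubule list (0.430 and 0.0833). Some other cell types are not excluded, since the loop and ureteric medians were -0.36 and -0.48 over 2 and 5 tested genes. The podocyte median was 0.17, and the endothelial median of 0.24 rested on 4 tested genes. Most loop, ureteric and endothelial markers below the filter were higher in both Six2Cre libraries, though near the floor. Aqp2 stood at 0.0995 and 0 in Six2TGC against 1.515 and 1.552 in Six2Cre, and Tmem52b at 0.0469 and 0 against 1.24 and 1.12. Ret, Wnt7b, Krt23, Sim2, Flt1 and Tek overlapped between the lines. Proximal tubule cells or their RNA in the Six2Cre libraries may be the source: a second list had a median of -1.44 over 10 tested genes of 28. Levels were low, with Slc34a1 at 14.6 and 6.24 in Six2Cre, and the GFP sort should remove such cells unless they carry GFP. Leaving out either Six2TGC library ended the call of Slc34a1 but left its log2 fold change at -2.96 and -3.29, against -3.13 with all libraries, and a biological difference between the lines was not tested.

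Wnt target and early nephron genes were higher and Cited1 lower in Six2TGC. The male library is argued against as the source, since without it the smaller of the changes in Wnt4 and Cited1 was 3.22 in size. Over 4 scalings the smallest size was 2.90. A factor per library moves both genes the same way, so changes in opposite directions could hardly both have shrunk. That comparison therefore decides little, and depth was not tested. A larger share of committed epithelium among the sorted Six2TGC cells stays open. The median over 15 committed nephron genes, 7 higher and 4 lower, was 0.38 (interval -0.71 to 1.38), between the bounds set for and against. The early nephron list also holds 9 of the listed genes. Over the 8 tested genes outside the fixed lists the median was 0.18 (interval -0.71 to 0.44). That is under the bound set against, but over few genes with a wide interval. A shift of progenitor state in the line itself may also account for the pattern and was not tested.

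Of the other 2 ways to split the 4 libraries into pairs, limma called 0 genes in each, against 2900 for the real split. Each of those splits puts a library of each line in both groups, so the difference between the lines adds to their spread and lowers their counts. With so few splits no share under 0.05 can be reached.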
